A study of Amorphotheca resinae with 20 samples.

How the data were processed

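RNA from mycelia of the filamentous fungus Amorphotheca resinae ZN1 was sequenced in 20 libraries, 2 for each of 10 groups. Per the labels' protocols, the fungus grew at 28 °C in potato-dextrose medium, with or without 1 inhibitor of the kind released when plant biomass is pretreated, and was collected at 4 h. The furan experiment held furfural at 1.0 g/L, 5-hydroxymethylfurfural (HMF) at 1.0 g/L and a control. The phenolic aldehyde experiment held vanillin, 4-hydroxybenzaldehyde and syringaldehyde, each at 0.1 g/L, and a control. The weak acid experiment held acetic acid at 2.0 g/L, formic acid at 4.0 g/L and a control. Doses were converted to mmol/L with molar masses from rdkit 2024.09.2. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with an Ion Proton RNA-Seq kit, and assays were done in duplicate. The labels do not state that duplicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

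The deposited values were whole-number read counts for 18830 identifiers, the same identifiers in the same order in each of 3 count tables. The aligner and the counting program are not given in the sources used here. The build named in the submitters' processing notes is Sscrofa 10.2, a pig assembly, which does not go with the ARZ identifiers of the deposited counts; which fungal gene models were used is therefore unknown. How reads shared by near-identical genes were counted is not stated either, so values of genes with such copies are uncertain. Of the 18830 identifiers, 0 matched a reference table of 9642 genes from the genome of another A. resinae strain (assembly Amore1). The count tables do not pair the identifiers with gene names or product descriptions. The planned tests of gene families by product description could not be run, and genes are reported by identifier only.

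Genes were kept with edgeR's filterByExpr within each experiment, which left 16398 genes for the furans, 17495 for the phenolic aldehydes and 16714 for the weak acids. The genes left out held 0.0407%, 0.0210% and 0.0246% of the counts. Counts were scaled with TMM (factors 0.942 to 1.05) and expressed as CPM, each gene's counts relative to its scaled library total. Each experiment was fitted with all of its groups in edgeR 4.0.16 (R 4.3.3), with robust quasi-likelihood F-tests, two-sided, and Benjamini-Hochberg adjustment over the genes tested. A gene was called changed at an adjusted p under 0.05. The common biological coefficient of variation was 0.120, 0.155 and 0.121 in the furan, phenolic aldehyde and weak acid experiments. Standard errors of log2 fold changes were taken from the F statistics. Compounds of one experiment were compared directly in the same fit, with 95% confidence intervals of the difference. Folds of named genes with at most 20 reads in a group were also computed from the summed reads, with exact 95% intervals that cover counting error only.

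The design, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes passed the test, changed at least 2-fold, had at least 10 CPM in a group, and had both libraries of one group on the same side of both libraries of the other. With no product descriptions, the rule took the 2 largest rises and the 2 largest falls among such genes in each comparison. Genes outside this rule are introduced as chosen after their values were seen. Overlaps between inhibitors were counted over the 16220 genes tested in all 7 comparisons, beside the overlap of independent lists. For the 5 pairs of comparisons that share control libraries, 10 draws of unchanged groups against those controls were simulated. The covariance of log2 CPM differences was also taken with 1 control library for each inhibitor of the pair. Correlations between fold changes are across genes with at least 10 CPM, and genes are not independent replicates.

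The tests were run on simulated counts with 200 changed genes per comparison. Over the 12 comparisons they recovered 50% to 82% of genes changed 2-fold and 87% to 96% of genes changed 4-fold, and 4.62% to 12.2% of the calls were false. Alternatives were median-of-ratios scaling, no filter, a minimum of 10 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, fits of only the 2 groups compared, a joint fit of all 3 tables, and a replicate block. Each library was also left out in turn, where a lone sample is assumed to vary like the other groups. For counts of changed genes in a comparison, only libraries of the 2 groups compared were left out. Figures were drawn with matplotlib 3.10.9.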

Results

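Transcript counts were collected from A. resinae ZN1 mycelia exposed to 7 inhibitors in 3 experiments, each with its own untreated control and 2 libraries per group. In the furan experiment the libraries held 11601181 and 13549363 counts for furfural (replicates 1 and 2), 13940715 and 13097870 for HMF (replicates 3 and 4), and 14107831 and 13133234 for the control. In the phenolic aldehyde experiment they held 26106956 and 14609602 for vanillin, 15058009 and 15534822 for 4-hydroxybenzaldehyde, 16914126 and 15250262 for syringaldehyde, and 17115633 and 21519549 for the control. In the weak acid experiment they held 16430097 and 18093936 for acetic acid, 20189482 and 18426561 for formic acid, and 18275236 and 19657606 for the control. Between 478 and 1210 of the 18830 genes had no read in a given library, and the 10 most abundant genes took 2.98% to 4.93% of its counts. Spearman's rho across genes between the 2 libraries of a group ran from 0.983 for syringaldehyde to 0.996 for 4-hydroxybenzaldehyde.

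**Figure D1:**
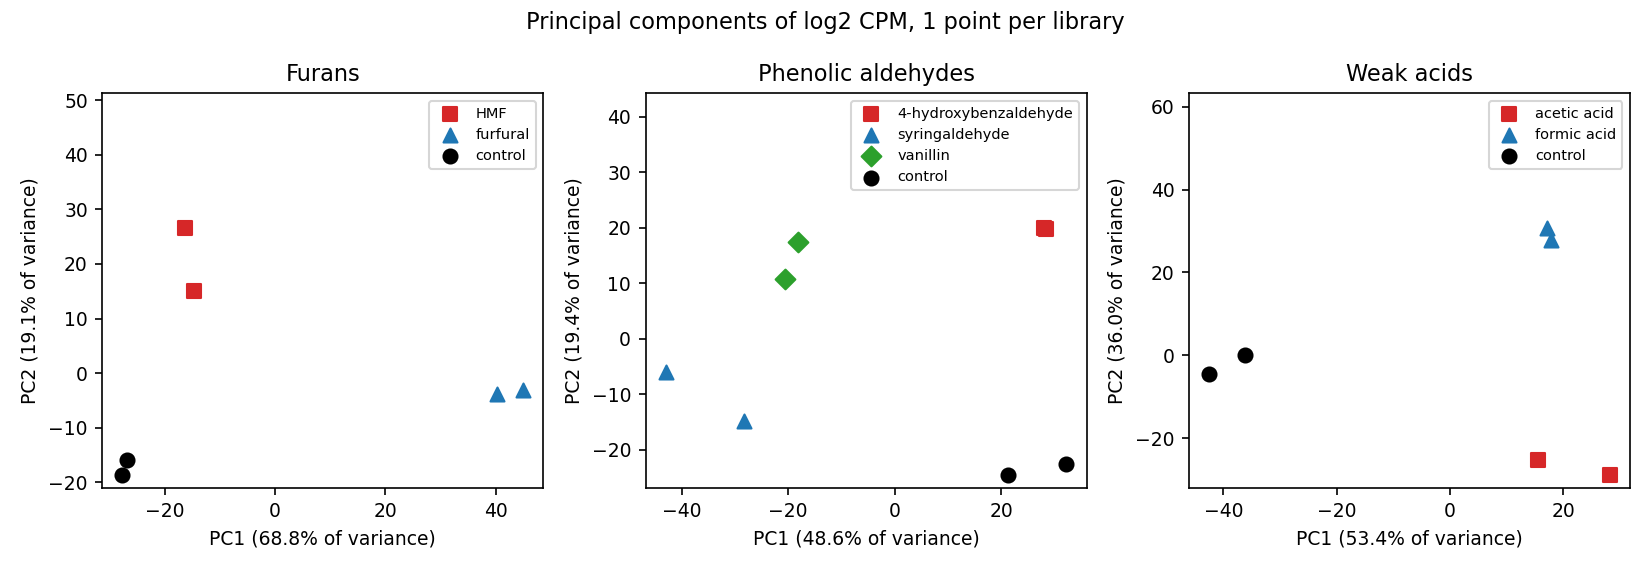
Principal components of log2 CPM in each experiment, with PC1 on the x axis and PC2 on the y axis (percent of variance in the axis labels); each point is a library, coloured by group. PC1 held 68.8% of the variance for the furans, 48.6% for the phenolic aldehydes and 53.4% for the weak acids.

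The first question was which genes responded to furfural. ARZ_2217_T1 rose from 7.16 ± 1.94 CPM in the control to 1118 ± 40.7 CPM with furfural (mean ± SD, n = 2, as for all levels), a log2 fold change of 7.29 ± 0.21 (SE). ARZ_13531_T1 rose from 4.39 ± 0.257 to 670.0 ± 54.0 CPM, a log2 fold change of 7.25 ± 0.19. ARZ_10440_T1 fell from 36.3 ± 11.4 to 0.962 ± 0.482 CPM, a log2 fold change of −5.19 ± 0.32, and ARZ_16712_T1 fell from 104 ± 4.81 to 3.47 ± 0.241 CPM, a log2 fold change of −4.91 ± 0.21. Adjusted p-values of these 4 genes (edgeR quasi-likelihood, Benjamini-Hochberg) ran from 1.33e-17 to 2.24e-11. Furfural changed 5619 of 16398 genes (34.3%), with 2851 higher and 2768 lower. At least 2-fold changes were seen in 1040 of the higher and 653 of the lower genes. Without furfural replicate 2 the count of changed genes was 3303.

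HMF carries a hydroxymethyl group that furfural lacks. With HMF, ARZ_7295_T1 rose from 1.251 ± 0.181 to 71.9 ± 1.85 CPM, a log2 fold change of 5.83 ± 0.26, and ARZ_15626_T1 rose from 1.59 ± 0.973 to 90.9 ± 17.8 CPM, a log2 fold change of 5.81 ± 0.26. ARZ_10440_T1 fell with HMF as well, to 3.84 ± 0.644 CPM (log2 fold change −3.23 ± 0.26), and ARZ_10438_T1 fell from 86.9 ± 38.8 to 8.06 ± 0.0301 CPM (−3.43 ± 0.40). Adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) ran from 2.99e-13 for ARZ_7295_T1 to 0.00225 for ARZ_10438_T1, whose call was lost without HMF replicate 4 (adjusted p = 0.121) or HMF replicate 3 (adjusted p = 0.209). HMF changed 1385 genes (8.45%), 820 higher and 565 lower, of which 163 and 104 changed at least 2-fold. The count was 2250 without HMF replicate 4, 753 without HMF replicate 3, 457 without control replicate 1 and 837 without control replicate 2.

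Set side by side at 1.0 g/L, which is 10.4 mmol/L furfural and 7.93 mmol/L HMF, the furans differed at some genes and not detectably at others. ARZ_2217_T1 and ARZ_13531_T1 were higher with furfural than with HMF by log2 8.08 ± 0.22 and 7.76 ± 0.20. ARZ_7874_T1 was lower with furfural (0.724 ± 0.482 against 11.9 ± 2.12 CPM, log2 difference −4.07 ± 0.36); the summed reads, 17 against 327, give a 17.9-fold difference with a 95% interval of 11 to 31.1. ARZ_7295_T1, which rose with both furans, was lower with furfural than with HMF by a log2 difference of −3.36 ± 0.21. ARZ_10440_T1 and ARZ_16712_T1 fell further with furfural, with log2 differences of −1.96 (95% interval −2.75 to −1.16) and −1.98 (−2.43 to −1.52). For ARZ_10438_T1 the difference was −0.90 with an interval of −2.02 to 0.21. Adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) of the 6 differing genes ran from 7.05e-18 to 0.000393. In all, 5607 genes differed, 2819 higher and 2788 lower with furfural; the count was 3724 without furfural replicate 1 and 3029 without furfural replicate 2. Of 11148 genes with at least 10 CPM, 8637 (77.5%) had an interval of the difference within 2-fold either way, and 324 lay wholly beyond 2-fold.

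**Figure D2:**
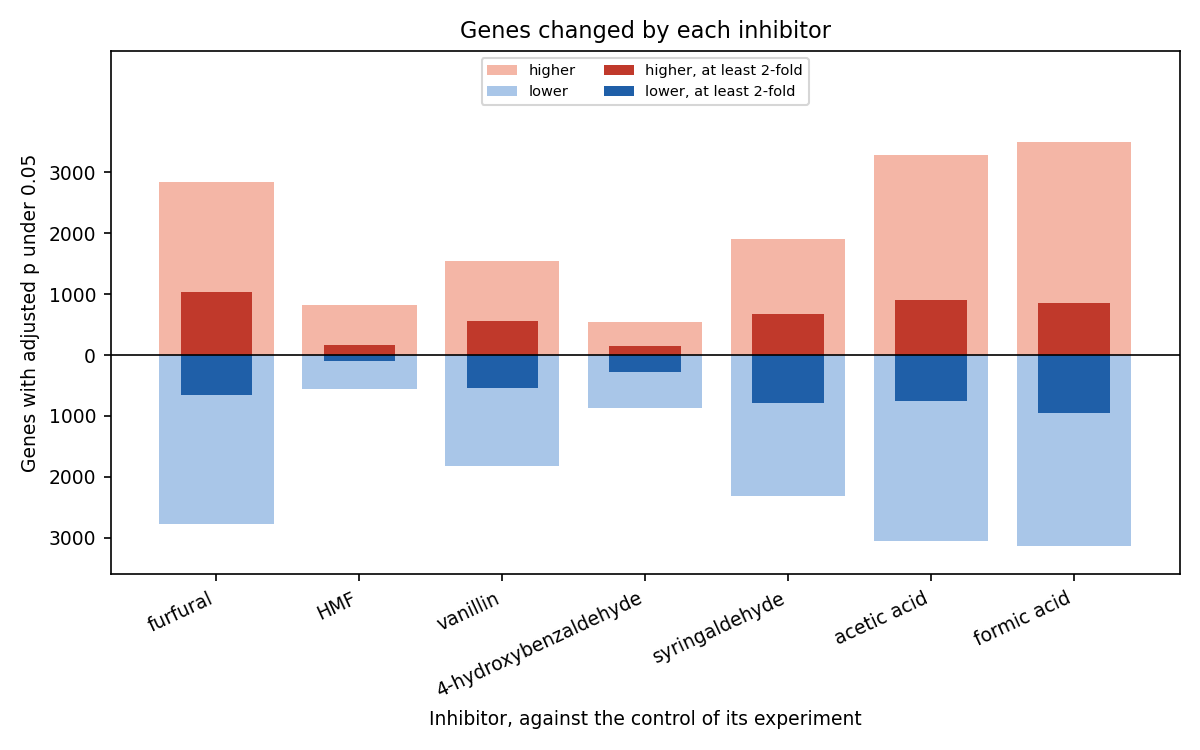
Number of genes changed by each inhibitor against the control of its experiment (y axis, genes with adjusted p under 0.05; higher above 0, lower below 0), with narrow bars for changes of at least 2-fold. Formic acid changed 6641 genes and HMF 1385.

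The phenolic aldehydes share a 4-hydroxybenzaldehyde core, to which vanillin adds 1 methoxy group and syringaldehyde 2. With vanillin, ARZ_11755_T1 rose from 1.58 ± 0.287 to 179 ± 8.95 CPM, a log2 fold change of 6.80 ± 0.20, and ARZ_15400_T1 rose from 46.4 ± 20.5 to 2515 ± 58.7 CPM, a log2 fold change of 5.76 ± 0.36. ARZ_10440_T1 fell to 0 and 5 reads in the vanillin libraries against 1151 and 1133 in the controls, 481-fold lower with a 95% counting interval of 206 to 1484. ARZ_10438_T1 fell from 190.3 ± 29.3 to 0.671 ± 0.684 CPM, a log2 fold change of −8.41 ± 0.43. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave p-values from 1.04e-09 to 8.35e-07. Vanillin changed 3367 of 17495 genes (19.2%), 1544 higher and 1823 lower, of which 566 and 547 changed at least 2-fold. The count was 842 without vanillin replicate 1 (476 higher and 366 lower), 1246 without vanillin replicate 2 (610 and 636) and 822 without control replicate 2 (382 and 440).

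With 4-hydroxybenzaldehyde, ARZ_800_T1 rose from 15.0 ± 5.35 to 1632 ± 91.2 CPM, a log2 fold change of 6.77 ± 0.34. ARZ_6554_T1 rose from 11.2 ± 3.13 to 560.4 ± 12.5 CPM, a log2 fold change of 5.64 ± 0.22. ARZ_10846_T1 fell from 49.6 ± 12.9 to 3.29 ± 0.609 CPM (log2 fold change −3.91 ± 0.30), and ARZ_4964_T1 fell from 435 ± 173 to 47.8 ± 2.78 CPM (−3.19 ± 0.42). Adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) ran from 9.49e-09 for ARZ_6554_T1 to 0.00140 for ARZ_4964_T1. The compound changed 1418 genes (8.11%), 544 higher and 874 lower, of which 157 and 272 changed at least 2-fold. The count fell to 114 without its own replicate 1 (56 higher and 58 lower), 142 without its replicate 2 (59 and 83), 358 without control replicate 1 (69 and 289) and 690 without control replicate 2 (239 and 451), so the share of lower genes depended on single libraries.

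Syringaldehyde also raised the 2 genes named above as higher with vanillin: ARZ_11755_T1 to 84.8 ± 1.69 CPM (log2 fold change 5.72 ± 0.20) and ARZ_15400_T1 to 1549 ± 412 CPM (5.06 ± 0.34). ARZ_10440_T1 fell to 3 and 2 reads against 1151 and 1133 in the controls, 380.3-fold lower with a 95% counting interval of 163 to 1172. ARZ_6862_T1 fell from 854 ± 273 to 6.02 ± 1.15 CPM, a log2 fold change of −7.15 ± 0.29. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave p-values from 5.82e-09 to 8.46e-07. Syringaldehyde changed 4218 genes (24.1%), 1909 higher and 2309 lower, of which 669 and 795 changed at least 2-fold. Without control replicate 2 the count was 1625 (589 higher and 1036 lower). The log2 difference between its 2 libraries had an SD across genes of 0.419, against 0.164 for 4-hydroxybenzaldehyde.

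The phenolic aldehydes were compared directly at 0.1 g/L, which is 0.819 mmol/L 4-hydroxybenzaldehyde, 0.657 mmol/L vanillin and 0.549 mmol/L syringaldehyde, so the molar doses differ. Against 4-hydroxybenzaldehyde, vanillin had more ARZ_11755_T1 (log2 difference 7.0 ± 0.21) and ARZ_5481_T1 (4.74 ± 0.24), and less ARZ_10438_T1 (−6.93 ± 0.43) and ARZ_10440_T1 (5 reads against 556, 148-fold lower, 95% counting interval 63.0 to 458). Syringaldehyde against 4-hydroxybenzaldehyde had more ARZ_11755_T1 (5.92 ± 0.20) and ARZ_6047_T1 (4.60 ± 0.30), and less ARZ_800_T1 (4.08 ± 1.96 against 1632 ± 91.2 CPM, log2 difference −8.64 ± 0.37) and ARZ_925_T1 (−6.83 ± 0.28). ARZ_800_T1 rose with vanillin too (log2 fold change 2.04) and fell with syringaldehyde (−1.87). Adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) of the named differences ran from 1.14e-09 to 2.99e-06. Vanillin and 4-hydroxybenzaldehyde differed at 3063 genes, 1555 higher and 1508 lower with vanillin. Without vanillin replicate 1 or 2 this count was 1198 (766 higher and 432 lower) or 801, and without 4-hydroxybenzaldehyde replicate 1 or 2 it was 617 or 791. Syringaldehyde and 4-hydroxybenzaldehyde differed at 3719 genes, 1784 higher and 1935 lower with syringaldehyde; without 4-hydroxybenzaldehyde replicate 1 or 2 the count was 1116 (399 higher and 717 lower) or 1161 (460 and 701). Of 11614 genes with at least 10 CPM, the interval of the difference lay within 2-fold for 8910 (76.7%) and 8543 (73.6%) in these comparisons, and wholly beyond 2-fold for 203 and 310.

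Vanillin and syringaldehyde, which differ by 1 methoxy group, differed at fewer genes in these fits. ARZ_10978_T1 was at 119 ± 10.9 CPM with vanillin and 1.16 ± 0.125 CPM with syringaldehyde, a log2 difference of 6.67 ± 0.24, and ARZ_925_T1 was at 269 ± 74.7 and 4.40 ± 0.281 CPM, a difference of 5.93 ± 0.27. ARZ_6047_T1 and ARZ_2979_T1 were lower with vanillin, by log2 differences of −3.66 ± 0.29 and −3.50 ± 0.31. ARZ_11755_T1 was higher with vanillin by 1.08 (95% interval 0.76 to 1.39). Adjusted p-values of the first 4 of these differences (edgeR quasi-likelihood, Benjamini-Hochberg) ran from 5.50e-09 to 1.36e-05. ARZ_6862_T1 (5.68) and ARZ_6337_T1 (95% interval 0.70 to 1.69, a gene chosen after its values were seen), which fell with both compounds, fell less with vanillin, and ARZ_5481_T1 rose more (1.05), with edgeR quasi-likelihood adjusted p-values of 5.66e-08, 0.00883 and 0.00981. Without vanillin replicate 2 the call was lost for ARZ_6337_T1 (0.0869) and ARZ_5481_T1 (0.0756), and without vanillin replicate 1 for ARZ_5481_T1 (0.0876). Some genes that moved with both were not shown to differ: ARZ_16712_T1 by −0.05 (−0.58 to 0.48), ARZ_10440_T1 by −0.33 (−2.70 to 2.05), and ARZ_15400_T1 by 0.70 (0.07 to 1.33), which missed the threshold after adjustment (edgeR quasi-likelihood adjusted p = 0.208). In all 830 genes differed, 497 higher and 333 lower with vanillin, and the interval lay within 2-fold for 10211 of 11614 genes (87.9%) and wholly beyond 2-fold for 139. The count was 263 without vanillin replicate 1 (219 higher and 44 lower), 346 without vanillin replicate 2 (255 and 91) and 2166 without syringaldehyde replicate 2 (1061 and 1105), so the excess of higher genes depended on single libraries.

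With acetic acid, ARZ_6462_T1 rose from 1.77 ± 0.261 to 40.6 ± 1.44 CPM, a log2 fold change of 4.51 ± 0.20. ARZ_7065_T1 rose from 18.2 ± 4.71 to 212 ± 53.7 CPM, a log2 fold change of 3.54 ± 0.52. ARZ_10440_T1 fell to 3 and 4 reads against 677 and 1268 in the controls, 253-fold lower with a 95% counting interval of 123 to 629.8, and ARZ_16712_T1 fell from 102 ± 25.1 to 1.76 ± 0.547 CPM, a log2 fold change of −5.85 ± 0.24. Adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) ran from 3.60e-11 for ARZ_16712_T1 to 0.00757 for ARZ_7065_T1, whose call was lost without control replicate 1 (adjusted p = 0.0926) or control replicate 2 (adjusted p = 0.0722). Acetic acid changed 6341 of 16714 genes (37.9%), 3285 higher and 3056 lower, of which 912 and 747 changed at least 2-fold. Without acetic acid replicate 2 the count was 3816.

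Formic acid raised ARZ_6462_T1 further, to 405 ± 58.2 CPM, a log2 fold change of 7.83 ± 0.21, and ARZ_11003_T1 rose from 2.82 ± 0.695 to 154 ± 11.9 CPM, a log2 fold change of 5.76 ± 0.19. ARZ_12937_T1 fell from 10.1 ± 0.561 to 0.962 ± 0.154 CPM (log2 fold change −3.37 ± 0.28), and ARZ_7133_T1 fell from 1777 ± 564 to 225 ± 15.0 CPM (−2.98 ± 0.21). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave p-values from 5.53e-14 to 2.27e-07. Formic acid changed 6641 genes (39.7%), 3500 higher and 3141 lower, of which 855 and 946 changed at least 2-fold. The count was 3985 without formic acid replicate 1 and 4037 without formic acid replicate 2.

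Acetic acid carries a methyl group that formic acid lacks, and their doses differed, at 33.3 and 86.9 mmol/L. ARZ_10440_T1 and ARZ_16712_T1 moved in opposite directions under the acids. ARZ_10440_T1 had 7 reads in all with acetic acid against 4045 with formic acid, 517-fold lower with a 95% counting interval of 250.5 to 1286, and rose with formic acid over its control (log2 fold change 1.11 ± 0.25). ARZ_16712_T1 was at 1.76 ± 0.547 and 336 ± 22.3 CPM, a log2 difference of −7.58 ± 0.25, and rose with formic acid over its control by 1.72 ± 0.17. ARZ_1634_T1 (10.7 ± 0.510 against 1.11 ± 0.523 CPM) and ARZ_15897_T1 (267 ± 22.3 against 28.2 ± 1.40 CPM) were higher with acetic acid, each by a log2 difference of 3.24, with SE 0.34 and 0.15. Adjusted p-values (edgeR quasi-likelihood, Benjamini-Hochberg) of these differences ran from 1.55e-12 to 3.53e-06. In all 4198 genes differed, 1974 higher and 2224 lower with acetic acid; of 11223 genes with at least 10 CPM the interval lay within 2-fold for 9601 (85.5%) and wholly beyond it for 210. The count of differing genes was 2460 without acetic acid replicate 2, 2064 without formic acid replicate 1 and 1629 without formic acid replicate 2.

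**Figure D3:**
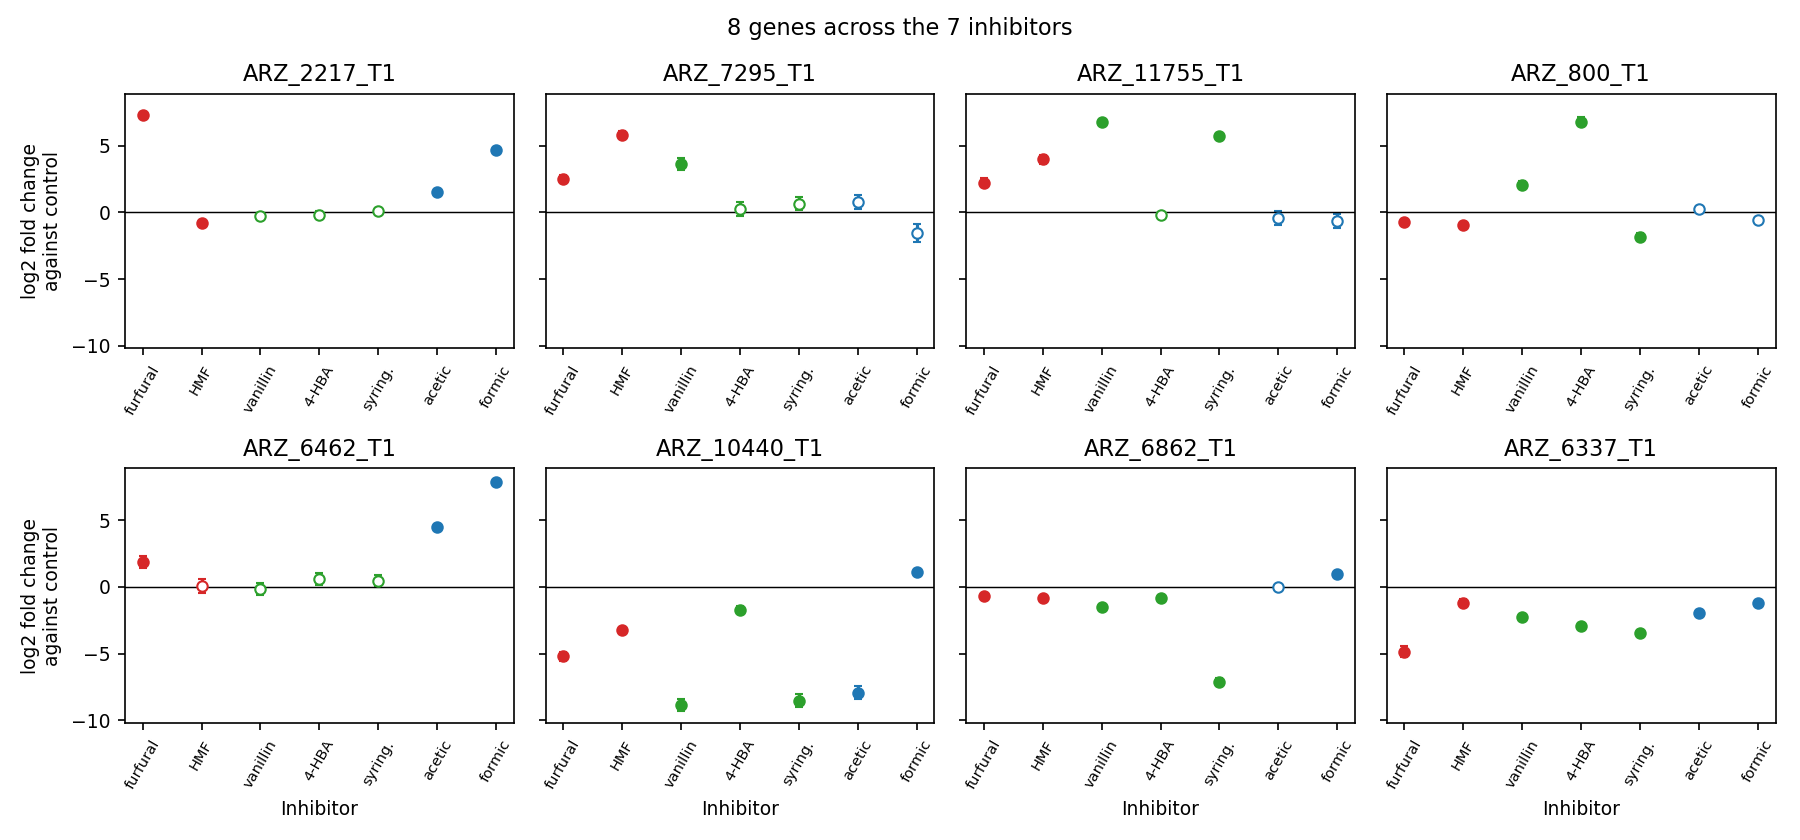
Log2 fold change of 8 genes (y axis) under each of the 7 inhibitors (x axis) against the control of its experiment; points are edgeR estimates with SE bars, filled where the adjusted p was under 0.05. ARZ_10440_T1 ran from −8.84 with vanillin to 1.11 with formic acid.

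Across the 7 inhibitors, several named genes moved under more than 1 class. ARZ_16712_T1 fell with 6 inhibitors, from −1.60 with 4-hydroxybenzaldehyde to −5.95 with vanillin on the log2 scale, and rose with formic acid (1.72). ARZ_2217_T1 rose with furfural (7.29), formic acid (4.69) and acetic acid (1.52). It was lower with HMF (−0.79, edgeR quasi-likelihood adjusted p = 0.0342), a call lost without HMF replicate 4 (0.149) or furan control replicate 2 (0.304), and with only those groups in the fit (0.147). ARZ_11755_T1 rose with vanillin (6.80), syringaldehyde (5.72), HMF (3.97) and furfural (2.24). ARZ_7295_T1 and ARZ_15626_T1 rose with HMF and furfural and also with vanillin (3.65 and 3.14), and ARZ_15626_T1 fell with formic acid (−2.23). ARZ_15400_T1 rose with all 3 phenolic aldehydes (5.76, 2.21 and 5.06 with vanillin, 4-hydroxybenzaldehyde and syringaldehyde) and fell with acetic acid (−2.93) and formic acid (−1.88). ARZ_10440_T1 fell with 4-hydroxybenzaldehyde by a smaller amount than with the other phenolic aldehydes (log2 fold change −1.70), a call lost without 4-hydroxybenzaldehyde replicate 1 (edgeR quasi-likelihood adjusted p = 0.0827) or control replicate 1 (0.0554). These cross-inhibitor values come from fits of separate experiments, and only compounds of the same experiment were compared directly.

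Of the 16220 genes tested in all 7 comparisons, 12569 changed in at least 1, and 4 fell in all 7, against 0.00284 for independent lists; part of the excess may come from controls shared within experiments. These genes, ARZ_6337_T1, ARZ_2129_T1, ARZ_6923_T1 and ARZ_7984_T1, are named after their values were seen. ARZ_2129_T1 and ARZ_6923_T1 may be copies of 1 gene, which was not tested, so the 4 may not be separate cases. They lie between 2 pairs of genes whose levels followed each other, ARZ_2067_T1 with ARZ_6862_T1 and ARZ_2151_T1 with ARZ_6947_T1. ARZ_6337_T1 had log2 fold changes from −4.85 with furfural to −1.17 with HMF, and the ranges were −2.08 to −0.61 for ARZ_2129_T1, −2.05 to −0.60 for ARZ_6923_T1 and −1.91 to −0.56 for ARZ_7984_T1. The number that rose in all 7 was 0 with edgeR quasi-likelihood adjusted p-values and 0 with DESeq2; at an unadjusted edgeR p under 0.05, 8 rose and 14 fell in all 7, and 5 fell with DESeq2. The count of 4 was 1 without furan control replicate 1, vanillin replicate 1 or 2, 4-hydroxybenzaldehyde replicate 1 or 2, or phenolic aldehyde control replicate 1. It was 2 without HMF replicate 3 or 4 or phenolic aldehyde control replicate 2. ARZ_6337_T1 lost its HMF call without HMF replicate 4 (edgeR quasi-likelihood adjusted p = 0.102), HMF replicate 3 (0.0519) or furan control replicate 1 (0.504). The gene left was ARZ_6923_T1 without furan control replicate 1 and ARZ_6337_T1 in the other 5 fits that left 1.

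Pairs of inhibitors were compared by the genes changed the same way in both. Vanillin and syringaldehyde shared 2038 genes, against 419 for independent lists, and 33 changed in opposite directions. Acetic and formic acid shared 3576 against 1269 (179 opposite), furfural and HMF 770 against 237 (90 opposite), vanillin and 4-hydroxybenzaldehyde 566 against 145 (42 opposite), and 4-hydroxybenzaldehyde and syringaldehyde 580 against 181 (71 opposite). Unchanged groups simulated against the shared controls gave 0 to 0.8 shared genes on average. As no gene was changed in the simulation, few could be called, so this is no baseline for the shared counts. The correlation of log2 fold changes across genes was 0.70, 0.63, 0.47, 0.41 and 0.32 for these 5 pairs. It was 0.50 for each pair in simulation. That value follows from unchanged groups of equal size sharing controls, so it is no baseline for r where genes respond. The covariance was 0.259, 0.237, 0.120, 0.108 and 0.0954, against 0.0225, 0.0165, 0.0168, 0.0223 and 0.0226 in simulation. With 1 control library given to each inhibitor of a pair, a split made after the result was seen, the covariance averaged over both assignments was 0.229, 0.217, 0.102, 0.0820 and 0.0696. The assignments gave 0.121 and 0.0434 for vanillin with 4-hydroxybenzaldehyde and 0.0413 and 0.0979 for 4-hydroxybenzaldehyde with syringaldehyde. With this split, r under the 2 assignments was 0.65 and 0.55 for vanillin with syringaldehyde and 0.58 and 0.52 for the acids. It was 0.39 and 0.37 for the furans and 0.48 and 0.13 for vanillin with 4-hydroxybenzaldehyde. For 4-hydroxybenzaldehyde with syringaldehyde it was 0.12 and 0.34. Part of each excess of shared genes may come from the shared controls, as the calls were not made again with 1 control library each.

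Between classes, which had separate controls, furans and phenolic aldehydes moved shared genes mostly the same way, and acids and phenolic aldehydes mostly opposite ways. ARZ_11755_T1 and ARZ_7295_T1 are examples of the former for some phenolic aldehydes only. ARZ_11755_T1 was not called with 4-hydroxybenzaldehyde (log2 fold change −0.20), nor ARZ_7295_T1 with 4-hydroxybenzaldehyde (0.26) or syringaldehyde (0.64). ARZ_15400_T1 moved opposite ways under the acids and all 3 phenolic aldehydes. For the 6 pairs of a furan with a phenolic aldehyde, 65.4% to 82.2% of shared genes went the same way and r ran from 0.16 to 0.32. For the 6 pairs of an acid with a phenolic aldehyde the share was 29.9% to 49.0% and r ran from −0.16 to 0.03; the correlation of the class means was −0.242 to −0.0663 with 1 control library per experiment, a split made after the result was seen. Among these pairs, 4-hydroxybenzaldehyde with acetic acid showed no clear opposite tendency. It had 330 genes the same way and 343 opposite, against 267 and 272 for independent lists. For an acid with a furan the share was 35.7% to 53.2% and r ran from −0.14 to 0.06. The 3 controls also differed from each other: 8630 of 17198 genes (50.2%) differed among them (edgeR quasi-likelihood F-test, Benjamini-Hochberg), so class and experiment are the same split and levels cannot be compared across experiments.

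**Figure D4:**
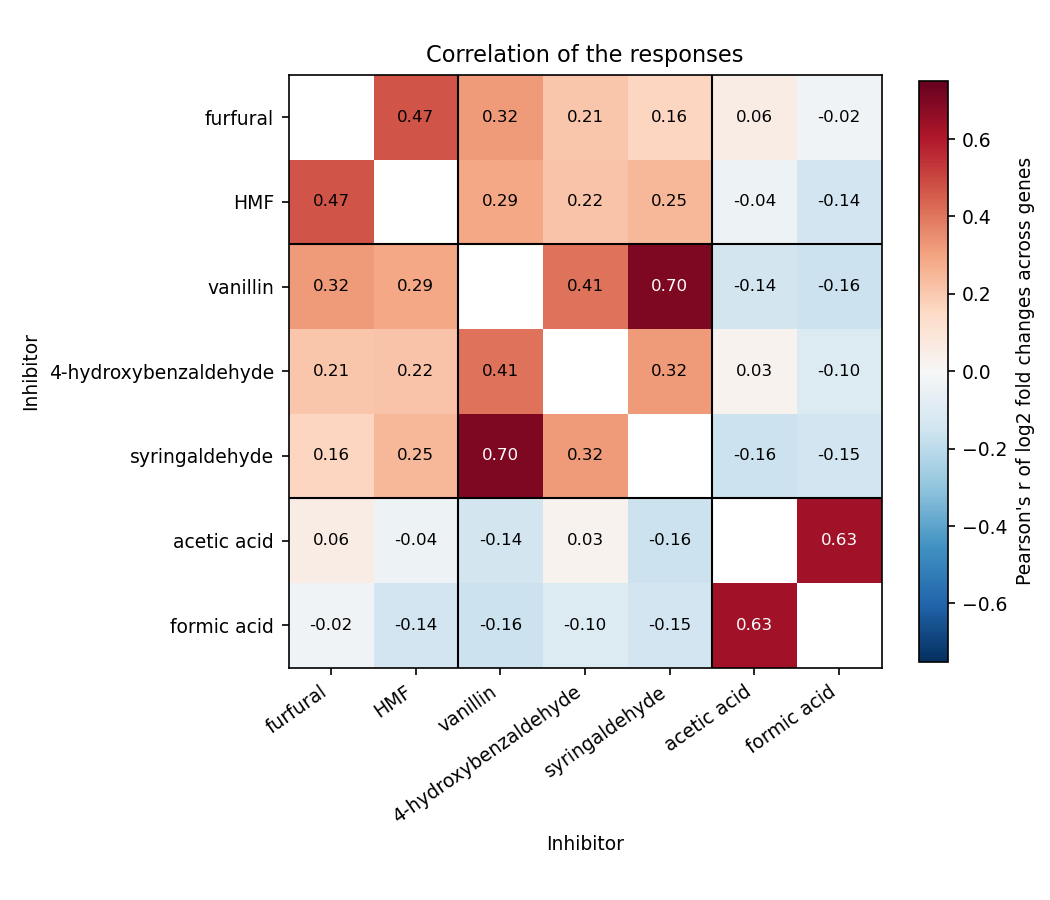
Pearson's r of log2 fold changes across genes for each pair of inhibitors (both axes), coloured and printed in each cell. Values run from −0.16 for vanillin with formic acid to 0.70 for vanillin with syringaldehyde. Pairs within a class share control libraries and pairs between classes do not, so their r cannot be compared directly.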

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

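The tests of the difference between inhibitor classes, their alternatives, the test with 1 inhibitor left out and the correlations with 1 control library were chosen only after the result was seen. The mean response to each class was estimated in a joint edgeR quasi-likelihood fit of all 20 libraries (17692 genes), and the difference between classes was tested as an interaction. It passed at 6597 genes for phenolic aldehydes and weak acids, 5476 for furans and weak acids and 2442 for furans and phenolic aldehydes. The last count was 1580 and 1261 without furan control replicate 1 and 2, 1624 without phenolic aldehyde control replicate 2, and the others stayed within 1.5 times. All genes called in opposite directions in the classes also passed the interaction, as opposite calls nearly ensure, so it adds nothing to the counts of such genes. Under phenolic aldehydes and weak acids, 1470 genes changed in opposite directions and 697 changed the same way. Opposite and same-way counts were 1240 and 379 without phenolic aldehyde control replicate 1, 631 and 391 without its replicate 2, 931 and 399 without weak acid control replicate 1, and 1660 and 1087 without syringaldehyde replicate 2. Under furans and weak acids, 784 changed in opposite directions and 603 the same way; these were 320 and 247 without furan control replicate 1, 409 and 381 without its replicate 2, and 484 and 367 without weak acid control replicate 1. Under furans and phenolic aldehydes, 227 changed in opposite directions and 974 the same way. Here the counts were 91 and 395 without furan control replicate 1, 80 and 631 without its replicate 2, 144 and 746 without phenolic aldehyde control replicate 1, and 117 and 543 without its replicate 2. They were 137 and 684 without furfural replicate 2 and 393 and 1211 without syringaldehyde replicate 2.

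Weak acids and phenolic aldehydes changed shared genes in opposite directions more often than in the same direction, and the correlation of their mean effects across 10917 genes was −0.165; with 1 control library per experiment it was −0.0663 and −0.0727 with phenolic aldehyde control replicate 1, and −0.242 and −0.213 with its replicate 2. With the 14 libraries thinned to 14607421 counts each the correlation was −0.166, so the pattern did not need unequal library sizes. Thinning moved it by at most 0.00119 with any choice of 1 control library per experiment. These genes had at least 10 CPM and still held many reads after thinning. The test could thus hardly have moved the correlation and decides nothing more about library size. A single inhibitor stays open. For noise of low-count genes, the correlation given next depended on the control library chosen. However, the 2 experiments shared no library, so independent counting noise would pull the correlation toward 0 and not below it. Among the 4383 genes with at least 50 CPM the correlation was −0.147. It was −0.0351 and −0.0492 with phenolic aldehyde control replicate 1 alone, and −0.236 and −0.214 with its replicate 2 alone. Among the 10917 genes it was up to 0.00630 with formic acid left out of the acid mean and phenolic aldehyde control replicate 1 alone. A difference between the controls of the experiments stays open too. Among the 1470 genes the median absolute log2 difference between experiments was 0.697 for treated groups and 0.659 for controls, a ratio of 1.06, against 1.00 for other genes. The difference between controls cannot be told apart from a biological difference between the classes, since each class had its own control. Both classes run against 1 control would test it.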

How the results depend on the processing

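The DESeq2 likelihood ratio test of the controls, the overlap counts other than those with median-of-ratios scaling or a 2-fold minimum, the split of the controls and all alternatives for the differences between classes were chosen only after the result was seen; the others were planned. Over 182 named gene results and 1967 alternatives, 1810 kept their direction and an adjusted p under the threshold, 157 went over it (highest adjusted p 0.504, edgeR quasi-likelihood) and 0 reversed. Of 89 alternative counts of changed genes, leaving libraries in, 79 were within 1.5 times the reported one. With only the groups compared in the fit, the count was 884 for HMF, 3200 for 4-hydroxybenzaldehyde, 2067 for syringaldehyde, 5861 for vanillin against 4-hydroxybenzaldehyde and 437 for vanillin against syringaldehyde. In the joint fit it was 897 for HMF, 2714 for 4-hydroxybenzaldehyde and 1507 for vanillin against syringaldehyde. Requiring a 2-fold change left 1 gene changed one way in all 7 comparisons and 16 of 202 changed one way in at least 5; it moved all 21 pair overlaps by over 1.5 times, by construction, and median-of-ratios scaling moved none of them so far. The cause of the other changes was not tested. No gene called in the reported fits was called in the opposite direction in an alternative, and no fit had a median log2 fold change over all genes larger than 0.0366 in size. The scaling holds that median near 0, so it cannot show an overall rise or fall. The ranges per comparison given next cover libraries of the 2 groups compared only. Leaving out another group's library of the same fit could move a count beyond its range.

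Leaving out 1 library gave 3303 to 4370 changed genes for furfural, 457 to 2250 for HMF, 822 to 2525 for vanillin, 114 to 690 for 4-hydroxybenzaldehyde, 1625 to 5853 for syringaldehyde, 3816 to 5646 for acetic acid and 3985 to 6021 for formic acid. For the direct comparisons it gave 3029 to 5579 for furfural against HMF, 617 to 1198 for vanillin against 4-hydroxybenzaldehyde, 263 to 2166 for vanillin against syringaldehyde, 1116 to 4905 for syringaldehyde against 4-hydroxybenzaldehyde and 1629 to 2882 for acetic against formic acid. Genes changed one way in all 7 comparisons numbered 1 to 4, and 3 to 5 in the alternative fits with all libraries. Those changed one way in at least 5 numbered 81 to 226, the lowest being 81 and 99 without phenolic aldehyde control replicate 2 and 1, 122 and 131 without vanillin replicate 1 and 2, and 128 and 127 without 4-hydroxybenzaldehyde replicate 1 and 2. The share of higher genes among those changed moved by up to 23.4 points, for vanillin against syringaldehyde without vanillin replicate 1. The interaction between classes passed at 1261 to 3515 genes for furans and phenolic aldehydes, 3958 to 6126 for furans and weak acids, and 4800 to 7122 for phenolic aldehydes and weak acids. Genes going opposite ways between classes numbered 80 to 393 for furans and phenolic aldehydes, 320 to 1019 for furans and weak acids, and 631 to 1674 for phenolic aldehydes and weak acids. The controls differed at 7974 genes in the likelihood ratio test and at 6777 to 8167 with 1 library left out.

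With the replicate number as a block the counts were 3122 for vanillin, 1243 for 4-hydroxybenzaldehyde, 3941 for syringaldehyde, 6482 for acetic acid and 6769 for formic acid, all within 1.5 times. For furfural the block was fitted without HMF and gave 7140, against 6411 without the block in the same libraries. With the block for all inhibitors but HMF, 3 genes fell in all 7 comparisons and 220 changed one way in at least 5. Of the reported 4, ARZ_6923_T1 with vanillin (edgeR quasi-likelihood adjusted p = 0.0536) and ARZ_2129_T1 with 4-hydroxybenzaldehyde (0.0560) went over the threshold and 2 stayed. The numbers mark no stated pairing, and same-numbered libraries deviated from their group means with correlations across genes of −0.124 to 0.169 over 10 pairs of groups. No paired analysis was possible for HMF because its libraries carry the numbers 3 and 4. The planned gene family tests were not run, as 0 identifiers matched a description.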

Other observations

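The test of partner order against shuffles, the count of neighbouring genes that changed together, the alternatives of the furan ratio and the genes named here were chosen only after the result was seen. In formic acid, ARZ_6463_T1 was the most abundant gene, at 1.28% and 1.30% of the counts, and rose from 2145 ± 458 CPM in the control to 13455 ± 318 CPM (mean ± SD, n = 2), a log2 fold change of 2.64 ± 0.21 (SE). ARZ_11002_T1 rose with it, from 698 ± 209 to 6455 ± 616 CPM (3.20 ± 0.22), and both rose with acetic acid (1.02 and 1.31) and furfural (1.01 and 1.44). The 2 may be copies of 1 gene, as set out below, which was not tested. ARZ_16710_T1 followed ARZ_16712_T1: it fell with 6 inhibitors, from −1.23 with 4-hydroxybenzaldehyde to −5.90 with vanillin on the log2 scale, and rose with formic acid (0.79). These changes passed the edgeR quasi-likelihood test in the reported fits and with each library left out. ARZ_6463_T1 was also higher with HMF (0.57) and ARZ_11002_T1 lower with syringaldehyde (−0.66), calls lost without HMF replicate 3 (edgeR quasi-likelihood adjusted p = 0.0993) or furan control replicate 1 (0.201), in the joint fit (0.0733) or with only the groups compared (0.0554) for the former. The latter was lost without phenolic aldehyde control replicate 1 (0.0598) or 2 (0.0691) or with only the groups compared (0.0978).

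Genes with consecutive identifiers that changed at least 2-fold in the same direction were counted in runs of 3 or more. Furfural had 77 such genes in 24 runs, against at most 35 in 100 shuffles; 1 of the 2 longest, ARZ_12678_T1 to ARZ_12682_T1, held 5 genes that rose by log2 1.11 to 5.30. Syringaldehyde had 50 against 24, including ARZ_924_T1 to ARZ_927_T1, which fell by log2 2.34 to 6.12, and ARZ_14126_T1 to ARZ_14129_T1, which fell by log2 3.93 to 5.73. Levels of ARZ_925_T1 and ARZ_926_T1 followed those of ARZ_14129_T1 and ARZ_14128_T1 over the libraries (r = 0.995 and 0.994). These 2 runs may thus be copies of 1 segment counted more than once, which was not tested. The shuffles treat all genes as separate and cannot show this. Acetic acid had 40 against 26, vanillin 22 against 9, HMF 3 against 0 and formic acid 42 against 42, and 4-hydroxybenzaldehyde had 0 against 3.

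Each of 11506 genes with at least 10 CPM was given a partner more than 20 numbers away. This was the gene whose levels followed its own most closely over the 20 libraries. For 99 of 7947 pairs of consecutive genes the partners were consecutive too, and these 99 pairs held 188 of the 11506 genes. Chance placement is argued against, since the highest of 100 shuffles was 4. Partners 1 number apart were 6.19 times as frequent as partners 2 apart. That argues against co-regulated clusters of more than 2 genes without matching gene order. Clusters of 2 neighbouring genes give partners 1 apart in either order, so they stay open. Random assignment of reads between indistinguishable copies is argued against by the split of reads in 71 matched pairs, which varied over libraries with a median chi-square per degree of freedom of 17.1. In 1903 other pairs that were each other's partner it was 14.8, so the split was no steadier in matched pairs. Mean levels were closer in matched pairs than in 1903 other reciprocal pairs (median absolute log2 difference 0.316 and 0.823, ratio 0.384), which is consistent with duplicated chromosome segments with 2 expressed copies of each gene, as a hypothesis. Segments duplicated within the genome and a pair of assembled haplotypes stay open and untested, as does a partial sharing of reads. Aligning the gene sequences would test them. Some genes named above lie in reversed order near matched pairs and may be copies, though they were not matched pairs themselves. ARZ_6462_T1 with ARZ_11003_T1 and ARZ_6463_T1 with ARZ_11002_T1 lie near ARZ_6481_T1 with ARZ_10979_T1. ARZ_10440_T1 with ARZ_16712_T1 lie near ARZ_10432_T1 with ARZ_16720_T1. Such genes were not shown to respond separately.

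Furfural changed 4.06 times as many genes as HMF; the ratio was 8.81 without furan control replicate 1, 8.58 without HMF replicate 3, 7.25 with only the groups compared in each fit, and 2.87 to 5.83 in the other alternatives. Sequencing depth is argued against, since it did not favour furfural, whose libraries held 11601181 and 13549363 counts against 13940715 and 13097870 for HMF. With the 6 libraries thinned to 11601181 counts the numbers were 5639 and 1396, a ratio of 4.04. Thinning removed only a small part of the counts and could hardly have moved the ratio, so it decides nothing. A larger spread between the HMF libraries is argued against as the whole cause by the SD of log2 fold changes net of replicate spread, 0.654 for furfural and 0.327 for HMF, a ratio of 2.00. A difference in molar dose, 10.4 against 7.93 mmol/L, and a difference between the compounds stay open and were not tested. A dose series would test them. The HMF libraries are numbered 3 and 4, and the labels do not say whether they were made together with the other furan libraries. A difference of that kind could not be tested.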
